A study of Bos grunniens and Bos grunniens x Bos taurus with 6 samples.

How the data were processed

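The series compared longissimus dorsi, the long muscle of the back, of yak and of cattle-yak, the hybrid of cattle and yak, with 3 samples in each group. Per the labels' protocols, total RNA was extracted with TRIzol and 1 µg of it went into a nanopore cDNA-PCR library (kit SQK-PCS109), in which cDNA of whole transcripts is amplified and sequenced as long reads. The submitters' processing notes name fastp, minimap2 and GSNAP, without versions or roles. The genome build and the software that counted the reads are not given in the sources used here. The identifiers in the deposited table carry either Ensembl names of Bos grunniens, the domestic yak, or names of the TALON type, given to transcripts assembled from the reads. Nothing in the labels says that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Sex, age, feeding and sequencing batch are likewise not given in the sources used here.

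The authors deposited whole-number read counts per transcript for the 6 libraries, and beside them CPM, which the authors scaled to each library's total of counted reads. The deposited CPM equalled the counts over the library total within 0.005. The table had 179856 transcripts, 6986 with a reference identifier and 172870 assembled, in 31044 genes, of which 10721 had a reference identifier. A further 132 lines held overflowing annotation text and no values. Transcripts without a gene identifier (61) held at most 0.0025% of a library's counts and were left out of the gene counts.

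Transcript counts were summed by gene identifier. A gene took the symbol that held most of its symbol-bearing reads, if that was at least 50% of them and 2% of all its reads, which named 13872 genes. Names of 6 genes, MYH7, ACTA1 and FABP3 among them, were taken from the deposited descriptions, and 22 list names were matched through an alias, both before any comparison of the groups. Where several identifiers shared a symbol (1728 symbols), the one with most reads stood for it. Gene copies and overlapping genes can share reads, and PCR reads without molecular identifiers are not independent molecules, so floors cover counting error only.

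Genes and transcripts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood test with robust dispersion), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Transcript usage was tested with edgeR's diffSpliceDGE on transcripts holding at least 5% of their gene's counts, in genes with 2 or more of them. The 32 gene lists were fixed before the data were examined, as were the main tests and the rule for named genes. Of them, 26 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. Shares of reads were compared with two-sided exact permutation tests, whose smallest possible p with 3 against 3 is 0.1. CPM values of genes and transcripts below are TMM-scaled. The SE of an edgeR log2 fold change was derived as its size over the square root of the test's F statistic. A fold against a group with no reads is a lower bound against a floor of 3 counts over the group. DESeq2 1.42.0 and limma-voom were alternatives, as were other scalings, filters, a replicate block, and fits without each library. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

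The rule for named genes took the 6 largest changes in each direction (mean of at least 10 CPM, groups not overlapping), up to 3 members of each called list and up to 2 of each other list, 12 genes of muscle, lipid and hypoxia biology, 4 transcripts per direction, and the 5 genes with the smallest p for usage. Of these, 1 gene and 1 transcript are not reported here. No gene of the table took the name MYH4, so the myosin share rests on MYH1, MYH2 and MYH7.

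Simulated data had the same means and library sizes, but 1 common dispersion for all features (0.0452 for genes, 0.0638 for transcripts). The rates need not hold where real features differ in dispersion. The gene test recovered 29.2% of genes changed by 1 log2 unit and 92.8% of those changed by 2, with 5.8% false calls. The transcript test recovered 17.2% and 87.1%, with 4.5% false calls. The usage test recovered all 100 changed genes, with 9.1% false calls. In these the main transcript was lowered by 2 log2 units and its lost reads given to the next one. Both transcripts held at least 10% of the gene's counts. Smaller shifts were not simulated, and the real called genes had a median largest share change of 13.2 points.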

Results

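Longissimus dorsi transcriptomes of 3 yak and 3 cattle-yak samples were compared by full-length nanopore sequencing. The libraries held 2350851, 2502603 and 2412511 counts in yak and 2382936, 2366057 and 2769106 in cattle-yak. At least 1 read was found for 103338 ± 634 transcripts in yak and 112320 ± 1530 in cattle-yak (SD, n = 3 each). The 10 most abundant genes, led by the actin gene ACTA1, whose name rests on 6.48% of its reads, took 37.1% ± 0.98 of counts in yak and 33.5% ± 1.36 in cattle-yak. Principal component 1, with 51.5% of the variance, separated the groups. No pair of libraries agreed within sampling noise.

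The first comparison asked which genes differ between the muscles. ANKRD2, a stretch-responsive ankyrin repeat protein of the sarcomere, rose from 54.4 ± 11.1 CPM in yak to 1139 ± 265 CPM in cattle-yak (SD, n = 3 each), a log2 fold change of 4.39 ± 0.23 (SE, edgeR adjusted p = 1.61e-07). MYBPH, a myosin-binding protein, rose by 3.90 ± 0.49 on the log2 scale, and UCP3, a mitochondrial uncoupling protein of muscle, by 3.55 ± 0.28, reaching 821 ± 164 CPM. MSS51, a mitochondrial protein of skeletal muscle, fell from 154 ± 22.5 to 11.0 ± 2.80 CPM (log2 fold change -3.79 ± 0.23). SELENOW, a small selenoprotein, fell from 626 ± 40.4 to 75.1 ± 16.4 CPM (-3.06 ± 0.19). KLHL23 (-3.17 ± 0.60) and CTXN3 (-2.76 ± 0.49) also fell.

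**Figure D1:**
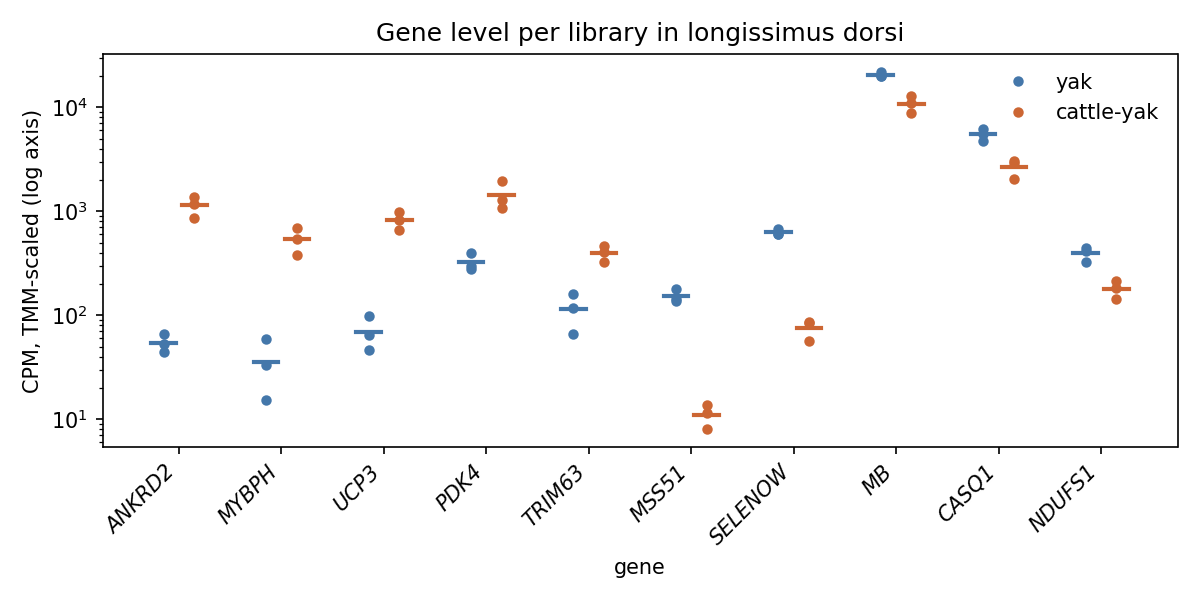
TMM-scaled CPM on a log axis for 10 genes named in the text, with 1 point per library and a line at the mean of the 3 libraries of each group. For every gene shown the 3 yak points and the 3 cattle-yak points do not overlap, as for MSS51, at 154 CPM on average in yak and 11.0 CPM in cattle-yak.

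Of 7504 genes tested, 484 rose and 464 fell in cattle-yak (edgeR adjusted p under 0.05), and 657 of these changed at least 2-fold. The balance differed by identifier: 271 reference genes rose and 362 fell, while 213 assembled genes rose and 102 fell. Among the largest changes, FAM13A rose by 4.09 ± 0.73 on the log2 scale and CILP, a cartilage matrix protein, had a log2 fold change of -3.63 ± 0.71. The FAM13A call was lost without yak 1, 2 or 3 (adjusted p up to 0.0813) and with limma-voom (0.0979). The CILP call was lost without yak 1, yak 3, cattle-yak 1 or cattle-yak 2 (up to 0.139) and with no low count filter (0.148). An assembled gene with the name TTN (TALONG000146285) rose by 5.03 ± 0.50 and one with the name CFDP2 (TALONG000143565) by 3.83 ± 0.52, but 96 and 205 identifiers carry these names. The assembled gene called VTCN1 (-3.60 ± 0.75), whose name rests on 6.0% of its reads, lost its call without yak 1, cattle-yak 1 or cattle-yak 2 (up to 0.121) and with limma-voom (0.133). The count of changed genes was 616 without yak 2 and 544 without yak 3. With library size alone as the scaling, which moved the median log2 fold change of all genes from 0.024 to 0.181, 676 genes rose and 296 fell.

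The fixed lists asked which muscle programmes moved. Genes of the respiratory chain encoded in the nucleus were lower in cattle-yak: of 46 tested, 7 fell, none rose and 39 did not pass, and 13 fell when adjusted over the list alone. NDUFS1, a subunit of complex I (log2 fold change -1.13 ± 0.18), ATP5MC2 of the ATP synthase (-1.09 ± 0.18) and COX6C of complex IV (-0.82 ± 0.15) fell (SE, n = 3 each). The list was called by camera (adjusted p = 4e-05), but not with an estimated correlation (adjusted p = 0.585). Of 19 genes of the tricarboxylic acid cycle, 7 fell, 1 rose and 11 did not pass (camera adjusted p = 0.0127, adjusted p = 0.631 with an estimated correlation), and 10 fell when adjusted over the list alone. SUCLA2 (-0.86 ± 0.17) and DLD (-1.04 ± 0.22) fell, whereas PDK4, the kinase that inhibits pyruvate dehydrogenase, rose by 2.14 ± 0.23. Without cattle-yak 2 the call of this list was lost (adjusted p = 0.0745), and both lists lost theirs with reference transcripts only (0.238 and 0.0739) and by the fry direction test (0.108 and 0.138). Of 10 mitochondrially encoded genes none passed (camera adjusted p = 0.42), although with no low count filter the list was called as lower (0.0375). The median log2 fold change over all genes was 0.241 in that fit, which can make a list look lower, against 0.024 in the main fit.

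Genes of muscle atrophy and proteolysis were higher: 7 of 23 rose, none fell and 16 did not pass (camera adjusted p = 0.0236, adjusted p = 0.585 with an estimated correlation). GABARAPL1, of the autophagosome, rose by 2.32 ± 0.26 on the log2 scale, TRIM63, the ubiquitin ligase MuRF1, by 1.78 ± 0.29 and FBXO40, another muscle ubiquitin ligase component, by 1.14 ± 0.16. The list kept its call without each of the 6 libraries. Of 12 antigen presentation genes, 2 rose, the immunoproteasome subunits PSMB10 (1.24 ± 0.26) and PSMB8 (1.64 ± 0.39), and 10 did not pass (camera adjusted p = 0.0335, adjusted p = 0.631 with an estimated correlation). Of the macrophage markers, 4 were tested, with a median log2 fold change of 1.41, and CTSS rose (1.44 ± 0.29). With no low count filter the macrophage list was called as higher (camera adjusted p = 0.000559). The antigen presentation list lost its call without yak 1, yak 2, cattle-yak 2 or cattle-yak 3 (adjusted p up to 0.135), by the fry direction test (0.264) and with library size alone as the scaling (0.052), and that of PSMB8 was lost without yak 1, yak 2 or cattle-yak 3 (up to 0.084).

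Of 21 calcium handling genes, 4 fell, none rose and 17 did not pass (camera adjusted p = 0.0412, adjusted p = 0.585 with an estimated correlation). CASQ1, the calcium store of fast fibres (log2 fold change -1.05 ± 0.19), SRL (145 ± 11.5 to 72.1 ± 21.8 CPM) and the calcium pump gene ATP2A1 (-0.69 ± 0.20) fell. The list lost its call without yak 1, yak 3 or cattle-yak 2 (adjusted p up to 0.118), with reference transcripts only (0.261), a mean of at least 10 CPM (0.0547) or library size alone (0.052), and by the fry direction test (0.126). ATP2A1 lost its call without the same libraries (up to 0.132) and with library size alone (0.0845).

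The other 21 lists tested were not called. Of 20 sarcomere and Z-disc genes, 7 rose, FLNC (1.72 ± 0.19) and NRAP (1.54 ± 0.18) among them, and 1 fell (camera adjusted p = 0.0651). Of 20 fatty acid oxidation genes, 4 rose and 4 fell (0.924), and of 10 lipid storage genes 4 rose (0.317), LPIN1 by 2.52 ± 0.35. Of 20 collagen and matrix genes, 4 fell (0.0894), with COL3A1 at -1.28 ± 0.24 and LUM at -1.46 ± 0.22. In the hypoxia list 2 of 12 fell (0.0894), one of them MB, the oxygen store myoglobin, from 20570 ± 1148 to 10850 ± 1945 CPM (-0.92 ± 0.17). In the redox and mitochondrial biogenesis list 1 of 21 rose, GPX3 (2.79 ± 0.39), and 3 fell (0.0702). In the purine and creatine list of 12, AMPD3 rose, with its name on 5.1% of its reads, and 3 fell, AMPD1 (-1.44 ± 0.21) among them (0.117). In the immediate early list 3 of 13 fell (0.116), with NR4A1 at -1.56 ± 0.24. Of 10 myogenic regulators 3 rose and 1 fell (0.657), of 5 developmental genes 1 rose (0.128), of 20 glycolysis genes 1 rose and 2 fell (0.116), and of 21 heat shock genes 1 rose, CRYAB (1.58 ± 0.19, adjusted p = 0.317 with assembled transcripts only), and 2 fell (0.918). Of 48 ribosomal protein genes 1 rose and 1 fell (0.786), and of 22 splicing genes 2 rose and 2 fell (0.872). QKI (1.55 ± 0.22) was among those that rose, with its name on 40.5% of its reads. Of its 403 cattle-yak reads, 229 lay in 1 transcript with no yak read. Leaving out 1 library brought 6 further lists past the threshold: sarcomere without cattle-yak 2 (0.0346), collagen without yak 2 (0.0226) or cattle-yak 2 (0.0111), redox without yak 1 (0.0361), immediate early without yak 2 (0.0196), glycolysis without cattle-yak 3 (0.0195), and macrophage without yak 1, yak 3 or cattle-yak 1 (adjusted p up to 0.0361). Without yak 2 the macrophage list had an adjusted p of 0.0565, and in the other fits without 1 library it had too few tested genes. With no low count filter 16 lists were called, 3 as higher and 13 as lower, the hypoxia (0.000344) and fast fibre (0.00721) lists among the lower ones. That fit held 31044 genes with a median log2 fold change of 0.241, against 0.024 in the main fit. Camera compares a list with the other genes, so this background alone can make a list look lower. The lipid storage list was called as higher by the fry direction test (0.0137) and the sarcomere list with a mean of at least 10 CPM (0.0411) or counts summed by symbol (0.0484). The ribosomal list was called as higher with reference transcripts only (0.016) and as lower with no low count filter (0.0215).

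Markers of other cell types were tested in the same way. None of 8 endothelial genes (camera adjusted p = 0.657) or of 8 smooth muscle genes (0.657) passed, 2 of 7 adipocyte genes fell (0.116), and 1 of 9 fibroblast genes rose, CLEC3B (1.22 ± 0.22), and 1 fell, LUM (0.657). Beside the macrophage list, the Schwann cell list had 3 tested genes, of which PMP22 rose (1.84 ± 0.23). Of 3 interferon genes and 1 lymphocyte gene none passed, and no gene of the erythroid or sex-linked list was tested.

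Fibre type was asked from the myosin heavy chains. MYH2, of fast oxidative fibres, fell from 26780 ± 2273 to 16970 ± 1180 CPM (SD, n = 3 each, log2 fold change -0.66 ± 0.15, edgeR adjusted p = 0.0135), a call lost without yak 2 (0.0697). Of its reads, 26.7% (83542) lay in transcripts named MYH1, more than the 28037 reads of that name in the MYH1 gene itself. Of the reads of the MYH7 gene, 44.3% lay in transcripts named MYH7, 21.9% in ones named PRM, 18.2% MYH8 and 9.8% MYH6. MYH7, of slow fibres, had a log2 fold change of 0.11 ± 0.18 (edgeR adjusted p = 0.744) and MYH1 one of 1.43 ± 0.43 (edgeR adjusted p = 0.0825), which passed without yak 3 (0.000113), without robust dispersion (0.0189) and with no low count filter (0.0425). The MYH7 share of myosin heavy chain reads was 10.1% ± 2.26 in yak and 14.6% ± 2.61 in cattle-yak, at least 12.9% in all 3 cattle-yak libraries and at most 12.7% in yak (two-sided exact permutation p = 0.1, the smallest 3 against 3 allows). The difference of 4.48 percentage points became 2.98 without cattle-yak 2. Of 15 slow fibre genes 1 rose and 3 fell, FHL1 (log2 fold change -1.16 ± 0.15) and MYBPC1 (5526 ± 205 to 2574 ± 184 CPM) among them (camera adjusted p = 0.537), and of 14 fast fibre genes 3 fell (0.116).

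Among the other genes chosen in advance, the hypoxia factors HIF1A (0.09 ± 0.27) and EPAS1 (0.11 ± 0.30), the fatty acid binding proteins FABP3 (-0.05 ± 0.32) and FABP4 (-1.03 ± 0.66), the desaturase SCD (-1.25 ± 0.42) and the mitochondrial coactivator PPARGC1A (-0.68 ± 0.40) did not pass (log2 fold change ± SE, edgeR adjusted p from 0.0676 to 0.94). SCD passed without yak 2 (0.0495) or cattle-yak 1 (0.0124) and with no low count filter (0.00303), and PPARGC1A without cattle-yak 1 (-1.29, 0.0392) and with assembled transcripts only (-1.79, 0.0141). FABP4 had 30, 36 and 41 reads in yak and 5, 44 and 10 in cattle-yak. Without cattle-yak 2, which holds the 44 reads, its log2 fold change was -2.45 and passed (0.00209), and with no low count filter it was -1.18 and passed (0.0162). MSTN, the inhibitor of muscle growth myostatin, had 5, 25 and 14 reads in yak and 2, 1 and 3 in cattle-yak, too few for the filter. With no filter its log2 fold change was -3.10 ± 0.63 (edgeR adjusted p = 7.11e-05).

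The next comparison took the transcripts. A QKI transcript (TALONT000399089), of an RNA-binding protein gene, had no read in yak and 229 in cattle-yak, at least 73.8-fold higher against a floor of 3 counts over the yak group. It carried no symbol of its own. The whole QKI gene had 120 reads in yak and 403 in cattle-yak, so its rise rested largely on this transcript. Transcripts of AAMDC (TALONT000926808) and TTN (TALONT001637479) were at least 67.7 and 59.3-fold higher in the same way. An LMOD3 transcript (TALONT000661824), of an actin-nucleating protein of thin filaments, fell from 321 ± 113 to 20.7 ± 7.88 CPM (SD, n = 3 each). Of 15805 transcripts tested, 1522 rose and 1400 fell (edgeR adjusted p under 0.05), of which 1985 lay in genes that changed the same way, 794 in genes that did not pass and 143 in genes that changed the other way. By identifier, 70 reference transcripts rose and 186 fell, while 1452 assembled ones rose and 1214 fell. With library size alone as the scaling 2003 transcripts rose and 1025 fell. With reference transcripts only, 194 of 1710 transcripts changed.

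Transcript usage was compared within genes. In SNRPD1, a core spliceosome protein gene, the transcript TALONT000433759 held 48.8% ± 0.80 of the gene's counts in cattle-yak and no read in yak (SD, n = 3 each), where 0 of 222 reads allows up to 1.35%. In NDUFC2, of complex I, the assembled transcript TALONT000927638 rose from 0.67% ± 0.12 to 47.7% ± 7.16, while the reference transcript fell from 94.7% ± 2.08 to 48.0% ± 9.58. In AAMDC, TALONT000926808, described as a Bos taurus protein, held 29.7% ± 1.24 in cattle-yak. An AAMDC transcript described as Bos mutus fell from 66.2% ± 3.12 to 36.7% ± 1.79. In TXNDC9, TALONT001074493, described as Bos mutus, rose from 0.30% ± 0.52 to 24.3% ± 2.77. The small GTPase gene RAB13 had 7 tested transcripts, and TALONT000705806 rose from 13.4% ± 4.18 to 27.3% ± 1.17. Usage changed in 154 of 1821 genes (edgeR adjusted p under 0.05), and 33 of them also changed in total. The test cannot tell a change of isoform from cattle alleles assembled as separate transcripts. The count of genes with changed usage was 73 without yak 1, 84 without yak 2, 70 without yak 3 and 69 without cattle-yak 2.

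**Figure D2:**
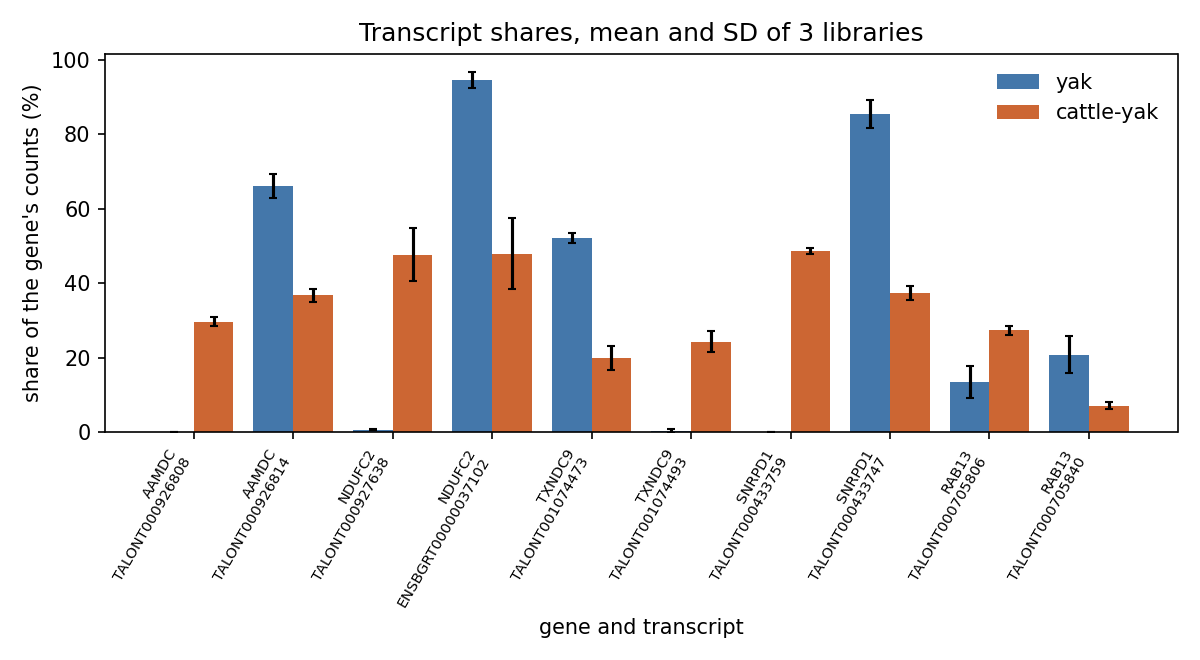
Share of each gene's counts in percent for 2 transcripts of each of the 5 genes with the smallest usage p, as the mean (bars) and SD (lines) of 3 libraries per group. The SNRPD1 transcript TALONT000433759 stands at 0 in yak and 48.8% in cattle-yak.

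The share of reads in transcripts with no reference identifier asked whether the reference covers both groups alike. It was 75.8% ± 0.26 in yak and 76.3% ± 1.30 in cattle-yak (SD, n = 3 each), a difference of 0.443 percentage points (two-sided exact permutation p = 0.9). Cattle-yak 2 had the highest share, 77.7%, and without it the difference was -0.304 points. Genes with no reference identifier held 8.34% ± 0.37 of counts in yak and 10.7% ± 1.81 in cattle-yak, higher in all 3 cattle-yak libraries than in any yak library. That difference was 2.37 points (exact permutation p = 0.1, the smallest possible), and 1.35 points without cattle-yak 2. Assembled transcripts made up 95.8% ± 0.06 of the transcripts detected in yak and 96.0% ± 0.02 in cattle-yak, 0.216 points more (exact permutation p = 0.1), again with no overlap between the groups.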

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

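Counts summed by symbol, reference genes only, assembled transcripts only, library size alone for the lists, and the share in genes with no reference identifier were chosen after seeing the data. Of 1352 values of named genes and transcripts, 1267 kept direction and side of the threshold, and none of the 67 called ones changed direction, although 19 lost their call under at least 1 alternative. Reference transcripts only, which leave fewer features to test, gave 194 changed genes, 194 transcripts, 1 gene with changed usage and 2 lists. A mean of at least 10 CPM gave 1651 transcripts. Usage was called in 292 genes with no minimum share, 78 with a minimum of 10% and 58 by the Simes method. Lists called were 0 with an estimated correlation, 2 by the fry direction test, 16 with no low count filter and 3 with library size alone; the cause was not tested. Without 1 library, counts ranged from 544 to 997 genes, 2053 to 3004 transcripts, 69 to 136 usage genes and 4 to 6 lists, and the MYH7 share difference from 2.98 to 5.78 points. The share in assembled transcripts differed by -0.020 points among transcripts that passed the filter and by -0.304 to 0.856 without 1 library. Among all genes, 1 called gene was called in the other direction with reference transcripts only. It was MSRB1 (1.53 to -0.57, edgeR adjusted p = 0.0336), singled out after its values were seen. Its transcript usage also changed, by up to 62.6 points (edgeR usage adjusted p = 2e-05), but the cause of the reversal was not tested. The log2 fold changes of named genes that turned sign were not called: with no filter MYH7 -0.020, EPAS1 -0.023 and HIF1A -0.031; with reference transcripts only PPARGC1A 0.24 and FABP3 0.22; with library size alone FABP3 0.10; with reference genes only FABP3 0.005. Without 1 library EPAS1 ranged from -0.16 to 0.46, HIF1A from -0.057 to 0.24 and FABP3 from -0.306 to 0.26.

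The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.038, -0.016 and 0.017. The replicate block gave 890 genes, 2597 transcripts, 109 usage genes and 5 lists, a MYH7 share difference of 4.48 points (exact sign-flip p = 0.25, the smallest possible) and 0.443 points for assembled transcripts. With it VTCN1 lost its call (adjusted p = 0.0639) and MYH1 passed (1.60, adjusted p = 0.0031). The MYH7 share with reference transcripts only could not be computed, since that gene has no reference transcript, and leaving out MYH4 changed nothing, since no gene had that name. The pseudocount alternative was for files without counts. Depth left genes with few reads, such as MSTN, out of the test.

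The 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 948 genes against at most 0 in another, 2922 transcripts against at most 1, and 154 usage genes against at most 1, so 1 split of 10 reached each. Every other split mixes yak and cattle-yak in both groups. A difference between yak and cattle-yak libraries then adds to the spread within groups, whatever its source, so few calls there are no support. The real split is taken up again for the lists. The real split called 5 lists against at most 6 in another, and 3 splits reached 5.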

Other observations

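The tests against transcripts read in both groups and with each gene counted once, the test of single cattle-yak libraries and both tests of the respiratory chain genes were chosen only after the result was seen. The other tests were fixed first, but the condition that a value must exceed its spread to count against an explanation was added to the allele, glucocorticoid and fibre tests after their values were seen.

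Some list members that the report counted without naming were chosen here after their values were seen. In the lipid storage list, which camera did not call (adjusted p = 0.317), PLIN5 rose by 2.02 ± 0.56 on the log2 scale and PLIN2 by 1.11 ± 0.33, both coats of lipid droplets (SE, n = 3 each). The transcription factors FOXO1 (2.22 ± 0.49) and FOXO3 (1.33 ± 0.33) were among the 7 proteolysis genes that rose. In the fatty acid oxidation list, also not called (0.924), DECR1 fell by 1.76 ± 0.24.

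Transcripts with at least 30 reads in cattle-yak and none in yak numbered 101, in 53 genes, of which 89 had reads in all 3 cattle-yak libraries, and the converse numbered 3. Other splits of the libraries gave at most 12, but each of them has cattle-yak libraries in both groups. A transcript read in all 3 cattle-yak libraries cannot be one-sided there, so the other splits add no support. In 1 random thinning to the smallest library, the ratio was still 31.0 (93 to 3), which argues against depth. Of the 101 transcripts, 89 lay in genes with enough cattle-yak reads to give a share. They held a median of 0.69% of their gene's cattle-yak counts, and at most 65.7%. A candidate explanation was that cattle alleles had been assembled as separate transcripts, which would match Bos taurus proteins more often than Bos mutus ones in the deposited descriptions. Of those matched to either species (8 to Bos taurus, 26 to Bos mutus), 23.5% matched Bos taurus, a difference of -26.5 points from the converse class (Fisher's exact p = 0.443). A description naming Bos indicus x Bos taurus, such as that of the TTN transcript TALONT001637479, counted as neither. Descriptions were also cut to a fixed length, which can remove the species of a long one. The percentages can therefore miss cattle matches. The rule fixed first counted a negative difference against the explanation, but the converse class had only 2 matched transcripts. From the 48.6% in transcripts read in both groups the difference was -25.1 points (Fisher's exact p = 0.00328). By the rule of that test this counts against the explanation, but transcripts of 1 gene are not independent. With each gene counted once, 6 of 13 matched Bos taurus, -4.8 points against the 50.9% of other genes (Fisher's exact p = 0.787), so the explanation stays open, as does the species difference itself, which was not tested. The sources used here do not say which sequence was matched.

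The proteolysis list, which does not hold PDK4 or UCP3, kept its call without each cattle-yak library (largest camera adjusted p = 0.047). That argues against 1 library as the source of its rise, although the list was not called with an estimated correlation (camera adjusted p = 0.585). For its rise together with PDK4 and UCP3, a glucocorticoid response at sampling may be a candidate explanation. It was examined on 11 other target genes written down beforehand, 8 of them tested. Their median log2 fold change of 0.17 lay at percentile 76.3 of 10000 matched random lists, short of the percentile of 95 set beforehand as speaking for it and under the 80 set as speaking against it, but with a bootstrap 95% interval from -0.42 to 0.70 the list decides neither way. Of its members only ZBTB16 passed (1.46 ± 0.25), and SGK1 had a log2 fold change of -1.01 ± 0.36 (edgeR adjusted p = 0.086).

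For the lower nuclear respiratory chain genes, a shift from slow to fast fibres would lower the MYH7 share, which was 4.48 points higher. That does not settle it, since the lowest cattle-yak library (12.9%) lay next to the highest yak one (12.7%). MYH7 itself had a log2 fold change of 0.11 ± 0.18, while MYH2, with most of the myosin reads, fell (-0.66 ± 0.15). A higher share is therefore not a rise of slow myosin. The MYH7 and MYH2 genes also mix names of several myosins. Of the slow fibre genes 3 fell, FHL1 (-1.16 ± 0.15) among them, and 1 rose, while of the fast fibre genes 3 fell and MYH1 had a log2 fold change of 1.43 ± 0.43, so a fibre shift stays open. Fewer mitochondria with all their transcripts could not be told apart from a change of nuclear genes alone. The mitochondrially encoded genes had a median log2 fold change of -0.13 with none past the threshold. With no low count filter their list was called as lower (camera adjusted p = 0.0375), in a fit whose median over all genes was 0.241. The lists rest on a preset correlation, and other splits of the libraries called as many of them.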
